A study of Rattus norvegicus with 109 samples.

How the data were processed

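Gene expression in rat pancreas and isolated acinar cells was measured on 109 Agilent 2-colour arrays in 22 groups, 16 of pancreas (80 arrays) and 6 of acinar cells (29 arrays). Per the series' design text, RNA of 3 rats per treatment was hybridised against RNA pooled from control rats, and 2 of these hybridisations were repeated with the dyes swapped. Which rats were repeated, and whether 1 pool or a pool per day was used, is not given in the sources used here. The labels give each control channel a day. Per the labels' protocols, acinar cells were prepared by collagenase digestion and centrifugation through albumin, and their purity was judged by staining for amylase and for a duct cytokeratin. Because the control is a pool, tests of ratios against 0 leave out the spread between control rats.

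Each deposited scanner file holds spot intensity values on a linear scale in the red and green channels, with local backgrounds. Per the file headers they were made with Agilent Feature Extraction 7.5.1 (60 pancreas arrays), 9.5.3.1 (20 pancreas arrays) and 10.7.3.1 (29 acinar arrays), and the submitters' processing notes name version 8.5.1.1. Pancreas files give mean pixel intensity and acinar files median pixel intensity, so the median was used for acinar cells where the plan had named the mean. The deposited files also hold log10 ratios of red over green, which per the file headers were made by the scanner software with spatial background subtraction and linear and lowess dye normalization. They entered only as an alternative. The authors deposited 20 tables of their own comparisons with a fold change and a p-value per feature, made with a tool that is not given in the sources used here. Their fold changes served for a check of direction and their probe names for naming. Their 40 columns of intensities per side of a comparison were not used here, nor were tables of APFO pancreas at days 1 and 28.

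Intensities were background-corrected with normexp (offset 50) and normalized within each array by loess, with control spots at weight 0, in limma 3.58.1 under R 4.3.3 with version 1.17.8 of data.table. Spots with outlier flags were left out and saturated spots kept. Repeated spots of a probe were averaged. A feature entered a fit if it was well above background in at least 1 channel on at least 3 arrays, and a gene was represented by its probe with the highest mean intensity. This left 19979 features in pancreas (4530 with a symbol), 35906 in acinar cells (7102 with a symbol) and 5213 on both array sets (2306 with a symbol). Probes were named through RefSeq accessions (3757 pancreas and 8022 acinar probes; the rat GRCr8 table was used for names only), the authors' deposited tables (968 and 310), gene names in the files' descriptions (279 and 279), or the same probe on the pancreas array (134 acinar probes). In all, 5004 of 20500 pancreas probes and 8745 of 41012 acinar probes received a name, so most features are unnamed here.

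The arrays with treated RNA in Cy5, 1 per rat, were fitted with limma: 48 pancreas arrays with 32 residual degrees of freedom, 17 acinar arrays with 11, and 65 arrays of both materials with 43. The swapped arrays entered only through the dye effect of each probe, the mean over groups of the half-sum of the red over green log ratios of both orientations, which was subtracted. A moderated F-test over all days, moderated tests at each day, and tests of differences between treatments, between materials and between days were adjusted by the Benjamini-Hochberg method and called at an adjusted p under 0.05. Where a probe was saturated or not well above background on every array of a group, a fold is given as a bound, from channel levels after loess and Aquantile normalization, and is open to dye bias. On 52 pancreas and 50 acinar probes a spot was saturated on at least 1 array.

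Before the data were examined, 31 gene lists, the tests, the alternatives and the rule for named genes were fixed. The lists were PPARα targets, peroxisomal fatty acid oxidation, mitochondrial fatty acid oxidation and ketogenesis, acinar digestive enzymes, protease inhibitors, acinar identity and secretagogue signalling, islet cells, duct cells, pancreatic injury and Reg family, ER stress and chaperones, amino acid response, cell cycle, cholesterol synthesis, fatty acid synthesis, fat cells, lymphocytes and lymph node, macrophages and granulocytes, fibroblasts and stellate cells, smooth muscle, endothelial cells, red blood cells, liver, intestine, oxidative stress and Nrf2 targets, xenobiotic metabolism, immediate early genes, heat shock proteins, interferon response, oxidative phosphorylation, ribosomal proteins, and circadian clock. Lists were tested with limma camera at a preset correlation of 0.01, adjusted over the 31 lists of a contrast, and again with an estimated correlation. Some genes belong to several lists.

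The rule for named genes took features with a symbol: per series the 5 highest and 5 lowest means over days among those past the F-test with 1 sign at every day, the 3 highest and 3 lowest at each day with 1 sign in every rat, per difference the 5 highest and 5 lowest, per list up to 4 members with the largest mean change, and always a fixed set where measured, among them Ehhadh, Cyp4a1, Pdk4, Angptl4, Cckar, Spink1, Amy2, Ins2 and Reg3b. Some genes of that set are not reported here. It named 139 genes for APFO, 129 for Wy50, 123 for Wy20 and 120 for DEHP in pancreas, and 81 and 83 for APFO and Wy50 in acinar cells. The text gives a selection of these, made after their values were seen and mostly of genes whose calls held under the alternatives, so it shows the steadier part of the named genes. Features of counts of 5 or fewer, and the genes given for the turned readings of APFO at day 7, were also chosen after their values were seen.

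Alternatives fixed in advance were the scanner software's log ratios, no background subtraction, median centring, no filter, all arrays with a dye term, no dye correction, only the treatments compared in the fit, the replicate number as a block, the date as a random block, every other probe of a gene, and leaving out each replicate number. The fit of all arrays counts the swapped arrays as separate rats, although they repeat hybridisations of the same rats. Its p-values can therefore be too low and its counts too high. Added after seeing the data were fits without day 1, without saturated features, without 1 DEHP array at day 7 on which 63.1% of spots carried an outlier flag (median over arrays 0.1905%), without 1 APFO acinar array at day 7 whose median signal in both channels was over 3 times that of the median acinar array (130 and 136.5), only on shared dates, and with APFO day 7 arrays turned or left out. The arrays fell on 13 dates, which were dates of data extraction for the 60 arrays of version 7.5.1 and scan dates for the others. In pancreas, Wy50 and DEHP shared dates at days 1, 7 and 28, APFO and DEHP at day 90, and Wy20 and most Wy50 arrays at day 90. In acinar cells APFO and Wy50 shared a date at each day.

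The fits were tested on simulated data with 50 features changed at each of 4 fold sizes. The simulated noise was independent between features and arrays, with no deviation of a shared control pool and no date effect. The false calls and list calls below therefore leave out errors of those kinds. At 1.25-fold, 92% were called for APFO in pancreas (6 false calls), 86% for APFO minus Wy50 (9), 72% for APFO minus DEHP (12), 66% for APFO in acinar cells (7), 26% for APFO minus Wy50 in acinar cells (8) and 78% for the APFO response between materials (8). At 2-fold 100% were called in each of these. A shift of the ribosomal protein list planted in simulated data was the only list called. The number of rats per group limits the precision throughout, and plots were drawn with matplotlib 3.10.9 under Python 3.11.15.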

Results

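Gene expression was measured in the pancreas of male CD Sprague Dawley rats that ate a powdered diet with 1 of 4 additions for 1, 7, 28 or 90 days. The additions were ammonium perfluorooctanoate (APFO, a fluorinated surfactant) at 300 ppm, the synthetic PPARα agonist Wyeth 14,643 at 50 ppm (Wy50) or 20 ppm (Wy20), and diethylhexyl phthalate (DEHP, a plasticizer) at 12000 ppm. PPARα is a nuclear receptor that switches on genes of fatty acid oxidation. The series is concerned with tumours of the acinar cell, the enzyme-secreting cell of the exocrine pancreas. Whole pancreas made up 16 groups with 80 arrays. Acinar cells isolated with collagenase from APFO and Wy50 rats at days 1, 7 and 28 made up 6 further groups with 29 arrays. Each 2-colour Agilent array set the RNA of 1 treated rat against pooled RNA of control rats, labelled with the same day. Of the 5 arrays in a group, 3 held treated RNA of separate rats in Cy5 and 2 repeated a hybridisation with the dyes swapped. The Wy50 acinar group at day 1 had 4 arrays, 2 of them with treated RNA in Cy5.

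The median signal per pancreas array ranged from 90 to 501.2 in the red channel and from 102 to 331.9 in the green channel. On acinar arrays the ranges were 90.5 to 440 and 88 to 223, apart from replicate 3 of APFO at day 7, which stood far above them at 2332 and 987. Treated RNA gave a signal well above background for 57.2% to 98.98% of probes on pancreas arrays and for 33.37% to 99.96% on acinar arrays, so dim genes were measured with less precision on some arrays. Values below are log2 ratios of treated over control RNA ± SE from limma, with n = 3 rats per day unless another n is given. Every gene value of a single day against control that is printed with an adjusted p had the same sign in all of its n rats. The adjusted p-values leave out the spread between control rats, because the control was pooled RNA. All counts rest on the moderated tests of limma at an adjusted p under 0.05.

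The first question was what APFO changed in the pancreas. With APFO, Dusp6, a phosphatase that switches off ERK kinases, was 5.88-fold higher than control at day 28 (2.56 ± 0.25, adjusted p = 2.67e-09), and it was still up at day 90 (1.82 ± 0.25, adjusted p = 2.44e-07). Clusterin (Clu), a secreted chaperone, fell by 1.11 ± 0.21 at day 28 (adjusted p = 5.61e-05) and was 5.57-fold lower than control at day 90 (-2.48 ± 0.21, adjusted p = 9.39e-12). Agpat1, an acyltransferase of phospholipid and triglyceride synthesis, reached 3.57-fold at day 90 (1.84 ± 0.16, adjusted p = 1.22e-11). Orm1, an acute-phase plasma protein, gained 1.64 ± 0.12 (adjusted p = 6.31e-13) at that day. The iron carrier transferrin (Tf) was 4.07-fold higher at day 90 (2.03 ± 0.22, adjusted p = 1.57e-09), as matrix Gla protein (Mgp) was by 1.83 ± 0.15 (adjusted p = 2.19e-12). The plasma protease inhibitor Mug1 stood at -1.82 ± 0.19 at that day (adjusted p = 1.08e-09). At day 28 the immediate early gene Egr1 (2.20 ± 0.44, adjusted p = 8.21e-05), the antiproliferative gene Btg2 (1.60 ± 0.27, adjusted p = 8.78e-06, n = 2) and Ptf1a, a transcription factor of acinar cells, were also higher (1.48 ± 0.21, adjusted p = 9.73e-07).

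Several of these ratios moved with the level of the control channel. For Dusp6 in APFO rats the treated channel lay at 9.01, 8.79, 9.21 and 9.44 log2 units at days 1, 7, 28 and 90, and the control channel at 8.96, 8.85, 6.91 and 7.87. The control channel of Agpat1 went from 9.57 and 10.34 at days 1 and 7 to 8.93 and 8.62 at days 28 and 90, with the treated channel between 9.91 and 10.58. That of Orm1 went from 9.75 and 10.72 to 9.02 and 8.83. For Clu the control channel was brightest at day 90 (11.05, against 8.49 to 9.14 before), and the treated channel lay between 8.05 and 8.59. For Mgp and Tf the treated channel was brightest at day 90 (11.18 and 10.44), with control levels of 9.44 and 8.42, and for Egr1 at day 28 (9.82, control 7.70). Levels of days 1 and 7 come from arrays of the same date, and those of days 28 and 90 from arrays of other dates. These comparisons between days were not tested.

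Among genes of mitochondrial fatty acid oxidation in APFO pancreas, on the mean over days, 13 of the 23 measured members rose, 2 fell and 8 did not pass (13 and 2 adjusted over the list alone; limma camera adjusted p = 0.00108, adjusted p = 0.601 with an estimated correlation). At day 90 the list had 11 members up and 0 down, in both adjustments (adjusted p = 0.00227, adjusted p = 0.37 with an estimated correlation). Decr1, which reduces unsaturated fatty acids for oxidation, was higher at day 1 (0.63 ± 0.10, adjusted p = 5.07e-05), day 28 (0.77 ± 0.10, adjusted p = 2.83e-07) and day 90 (0.63 ± 0.10, adjusted p = 4.38e-06). Acadsb, an acyl-CoA dehydrogenase, gained 0.91 ± 0.09 at day 90 (adjusted p = 7.8e-10) and Aldh3a2, a fatty aldehyde dehydrogenase, 1.13 ± 0.17 (adjusted p = 1.33e-06). Pdk4, the kinase that restrains pyruvate dehydrogenase, rose by 0.33 ± 0.05 (adjusted p = 2.57e-06) at that day. Ehhadh, a bifunctional enzyme of peroxisomal oxidation and a classical PPARα target of liver, went the other way at day 28 (-0.47 ± 0.10, adjusted p = 0.000299). The whole list of PPARα targets was not called in APFO pancreas, with 11 of 32 members up and 4 down in both adjustments (adjusted p = 0.267, adjusted p = 0.84 with an estimated correlation). Neither was peroxisomal fatty acid oxidation, with 10 of 22 up and 7 down (adjusted p = 0.533).

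Digestive enzyme transcripts fell in APFO pancreas under loess normalization, a direction that turned under median centring and without saturated features. On the mean over days, 0 of 20 measured members rose, 13 fell and 7 did not pass in both adjustments (adjusted p = 0.00108, adjusted p = 0.792 with an estimated correlation). The list was lower at day 28, with 12 members down and 2 up (adjusted p = 0.0407, adjusted p = 0.879 with an estimated correlation), and at day 90, with 14 down and 0 up (adjusted p = 0.00227, adjusted p = 0.818 with an estimated correlation). Without saturated features neither day was called. The fixed list of pancreatic injury and Reg family genes also fell, with 8 of 18 members down and 1 up in both adjustments (adjusted p = 0.0172, adjusted p = 0.0496 with an estimated correlation). Its call ended without replicate 1 (adjusted p = 0.123) and under median centring (adjusted p = 0.0513). The mean over days includes day 1, where the control pool was bright for Reg3a and Reg3b, as given below. Osteopontin (Spp1), a member of that list, fell by 1.17 ± 0.17 at day 90 (adjusted p = 7.4e-07). Oxidative phosphorylation genes were up at day 28, with 7 of 11 members higher and 0 lower (adjusted p = 0.0123, adjusted p = 0.104 with an estimated correlation), among them Cox5b (0.87 ± 0.10, adjusted p = 5.2e-08), a subunit of cytochrome c oxidase. The stress-induced pseudokinase gene Trib3 gained 1.03 ± 0.21 (adjusted p = 0.000166) at day 28.

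The Reg3 genes encode secreted lectins that are strongly induced in pancreatitis. At day 1 the log ratios of Reg3a and Reg3b were very low in all 4 pancreas series, and at that day the control pool itself was bright for both. Reg3a stood at -6.32 ± 0.69 with APFO (adjusted p = 7.52e-08), and was at least 38.3-fold lower than the saturated control spots with Wy50, 40.4-fold with Wy20 and 76.6-fold with DEHP (adjusted p = 3.24e-06, 6.44e-06 and 7.91e-08). Reg3b was at least 142-fold lower with Wy50, 129-fold with Wy20 and 194.5-fold with DEHP (adjusted p = 1.56e-07, 3.95e-07 and 2.61e-08), and with APFO the 1 array that measured it had a treated level of 10.68 and a control level of 16.64. The control channel of these genes lay between 16.14 and 16.89 log2 units at day 1, where it was saturated in the Wy50, Wy20 and DEHP series, and between 7.96 and 11.19 at the later days. Reg1a at day 1 was at least 6.73-fold lower with APFO (adjusted p = 2.48e-05). At day 90, Reg3b was 14.77-fold lower than control in APFO rats (-3.89 ± 0.78, adjusted p = 0.000117), where the control level was 10.77 ± 0.34 and the treated level 6.93 ± 0.39 (SD). The treated levels at day 90 were 10.08 ± 3.84 in Wy50 rats, 10.72 ± 2.74 in Wy20 rats and 10.85 ± 1.06 in DEHP rats (SD, n = 3 each).

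**Figure D1:**
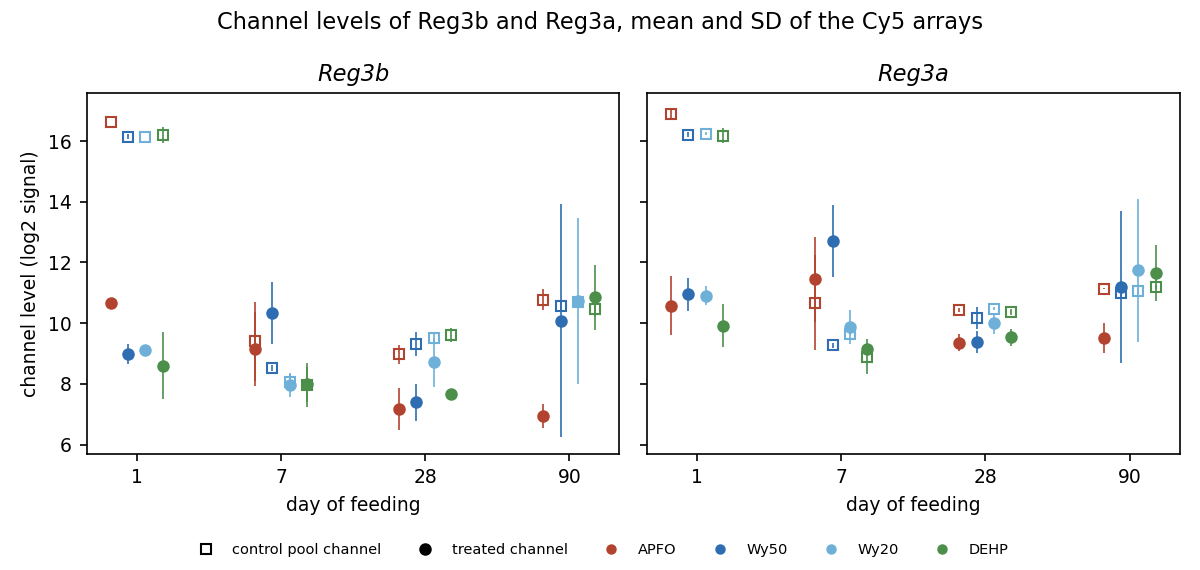
Channel levels (log2 signal) of Reg3b and Reg3a in pancreas by day of feeding, with open squares for the control pool channel, filled circles for the treated channel, and bars for the SD of the Cy5 arrays (3, except 1 for Reg3b with APFO at day 1 and 2 for Reg3b at day 7 and Reg3a at day 28 with APFO). The control channel lies at 16.14 to 16.89 at day 1 and at 7.96 to 11.19 afterwards, and treated Reg3b at day 90 is lowest with APFO (6.93).

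With APFO, 14504 of 19979 features in pancreas differed from the control pool at any day by limma's F-test. On the mean over days 7551 of these were higher and 6953 lower, but only 7 by over 2-fold. Tested on that mean alone, 51.1% of all features passed, a rate to set beside the list counts above. A deviation of the pool itself counts as a change here and in the other series. By day, 4316 features passed at day 1 (2133 higher, 2183 lower), 175 at day 7 (150 higher, 25 lower), 9889 at day 28 (5003 higher, 4886 lower) and 8601 at day 90 (4501 higher, 4100 lower; 161 over 2-fold). Without replicate 2 the count at any day was 9266, and with only the APFO groups in the fit 6219. The responses differed between days for 11203 features.

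At day 7 the direction of the APFO arrays is not settled. Array 1 (Cy5) and array 4 (Cy3) ran against arrays 2, 3 and 5, with correlations between the Cy5 arrays of the group from -0.653 to 0.75 across features. With arrays 1 and 4 turned, 8289 features passed at day 7 (4381 higher, 3908 lower), and with arrays 2, 3 and 5 turned instead, 5171 (2240 higher, 2931 lower). As labelled, arrays 1 and 4 correlated at -0.304 and -0.364 across 200 features with the reversed day 7 difference of the control channel of the other series, and arrays 2, 3 and 5 at 0.187, 0.325 and 0.104. With the mean of APFO days 1 and 28, arrays 1 and 4 correlated at -0.539 and -0.502. Arrays 2, 3 and 5 correlated with it at 0.591, 0.566 and 0.474. These values argue against turning arrays 2, 3 and 5, if the series shared that control and the day 7 response was like that of days 1 and 28. Turning arrays 1 and 4 keeps the 3 Cy5 arrays of a pancreas group, while turning arrays 2, 3 and 5 leaves 2. The APFO F-tests, means over days and list calls on those means in pancreas include the day 7 arrays as labelled. The amino acid transporter Slc7a8 stood at 1.59 in the first reading (adjusted p = 1.67e-10) and at -1.51 in the second (n = 2, adjusted p = 4.36e-08, limma). The enzyme genes Pnlip, Pnliprp1 and Cpb1 were saturated on all 5 arrays, so no ratio is given for them. The digestive enzyme list had 14 of 20 members down and 2 up in the first (adjusted p = 1.59e-06, adjusted p = 0.452 with an estimated correlation) and 14 up and 0 down in the second (adjusted p = 5.2e-18, adjusted p = 0.172 with an estimated correlation).

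**Figure D2:**
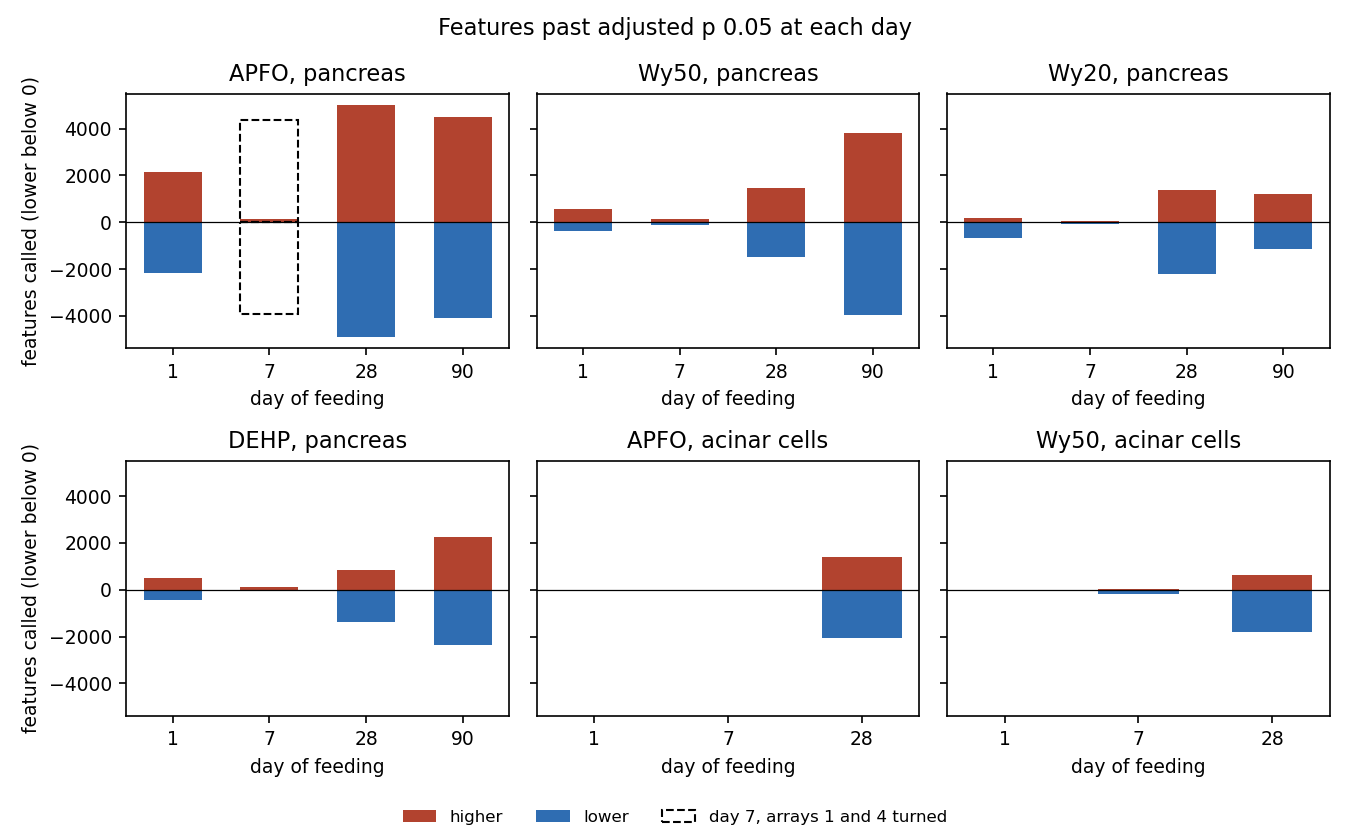
Features called at each day of feeding (count, limma adjusted p under 0.05), with bars above 0 for features higher and bars below 0 for features lower than the control pool in each series. Day 28 has the most calls in APFO pancreas (9889) and day 90 in Wy50 pancreas (7785), and the APFO bar at day 7 (175) rests on arrays whose direction is not settled.

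The second question was what the PPARα agonist Wy changed. In Wy50 pancreas, Dusp6 was higher at day 28 (2.38, adjusted p = 1.59e-06, n = 2) and day 90 (1.74, adjusted p = 6.28e-07), Agpat1 at day 28 (1.37, adjusted p = 1.65e-07) and day 90 (1.80 ± 0.16, adjusted p = 4.71e-11), and Orm1 at day 28 (1.63, adjusted p = 9.17e-12) and day 90 (1.71 ± 0.12, adjusted p = 3.93e-12). Azgp1, a secreted lipid-mobilizing glycoprotein, gained 1.03 at day 28 (adjusted p = 4.23e-07) and 1.39 at day 90 (adjusted p = 5.52e-11). The clotting protein gene F2 was up at day 28 (1.87 ± 0.26, adjusted p = 3.88e-06), as was Nsg1 (1.38 ± 0.12, adjusted p = 2.14e-10). Clu fell by 1.59 at day 28 (adjusted p = 2.6e-06) and by 1.68 at day 90 (adjusted p = 4.15e-08). At day 90, Mug1 (-1.71, adjusted p = 3.56e-09), the cholesterol-esterifying plasma enzyme Lcat (-1.41 ± 0.11, adjusted p = 2.42e-11) and Ugt2a1, a glucuronosyltransferase (-1.32 ± 0.13, adjusted p = 9.8e-10), were lower. At day 90, Cd74 was at -0.94 (adjusted p = 7.94e-11) and B2m at -0.79 (adjusted p = 0.000135). The islet hormone gene Sst gained 0.83 at that day (adjusted p = 2.18e-05). Here too the control channel moved: at days 1, 7, 28 and 90 the treated channel of Dusp6 lay at 10.39, 8.92, 9.04 and 9.30 and the control channel at 9.94, 9.44, 6.92 and 7.82. For Orm1 the treated levels were 11.79, 11.99, 11.09 and 10.57 and the control levels 11.10, 11.81, 9.43 and 8.82. For Agpat1 they were 10.84, 10.80, 10.48 and 10.66, and 9.96, 10.51, 9.08 and 8.83. The control levels of F2 (8.26 and 8.53 at days 1 and 7, 7.09 at day 28) and Nsg1 (12.39 and 12.23, then 11.33) were also lower at day 28.

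Mitochondrial fatty acid oxidation genes rose with Wy50, with 11 of 23 members up, 1 down and 11 not passing on the mean over days in both adjustments (adjusted p = 0.00805, adjusted p = 0.711 with an estimated correlation). At day 90, 13 were up and 1 down (14 and 2 adjusted over the list alone; adjusted p = 0.00216, adjusted p = 0.88 with an estimated correlation), among them the electron transfer flavoprotein Etfb (0.71, adjusted p = 9.69e-06) and Pdk4 (0.35, adjusted p = 1.42e-06). Ehhadh fell by 0.51 at that day (adjusted p = 0.000133). The PPARα target list was not called, with 8 of 32 up and 5 down (9 and 5 adjusted over the list alone; adjusted p = 0.396, adjusted p = 0.744 with an estimated correlation). Digestive enzymes had 10 of 20 members down and 0 up in both adjustments (adjusted p = 0.00351, adjusted p = 0.711 with an estimated correlation), and at day 90 9 down (adjusted p = 0.00298, adjusted p = 0.88 with an estimated correlation). Median centring and leaving out saturated features ended both calls. On the mean over days, which includes day 1 with its bright Reg3a and Reg3b control, injury and Reg family genes fell. In both adjustments 8 of 18 members were down and 1 up (adjusted p = 0.00805, adjusted p = 0.0369 with an estimated correlation). At day 28, 5 members were down and 1 up (8 and 1 adjusted over the list alone, adjusted p = 0.000814, adjusted p = 0.00321 with an estimated correlation). None of the alternatives ended that call, but none of them replaced the control pool. The control levels of Reg3b and Reg3a in that series were 9.31 and 10.17 at day 28. They were 8.53 and 9.27 at day 7 and 16.14 and 16.21 at day 1. Ribosomal protein genes had 8 of 37 members up and 0 down (7 and 0 adjusted over the list alone; adjusted p = 0.0286, adjusted p = 0.711 with an estimated correlation), a call that ended without replicate 2 (adjusted p = 0.109) or 3 (adjusted p = 0.0879). At day 90, 18 of them were up and 0 down (19 and 0 adjusted over the list alone; adjusted p = 0.000304, adjusted p = 0.88 with an estimated correlation), with Rps16 at 0.82 (adjusted p = 2.04e-10).

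Tested on the mean over days, 37.7% of all features passed in Wy50 pancreas. At any day 8379 features differed from the control pool (4217 higher, 4162 lower), with 924, 236, 2920 and 7785 at days 1, 7, 28 and 90. Median centring gave a count of 4105, and leaving out replicate 2 or 3 gave 4248 and 4108.

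At the lower level of Wy, Dusp6 was 10.9-fold higher at day 28 (3.45 ± 0.25, adjusted p = 5.06e-12) and up at day 90 (1.41, adjusted p = 0.000426). Its treated level at day 28 was 10.14, against 9.45 and 8.29 at days 1 and 7, and its control level 6.94, against 9.48 and 9.03. Azgp1 gained 1.14 at day 28 (adjusted p = 5.32e-08) and 1.14 at day 90 (adjusted p = 2.05e-07), and Btg2 (1.49, adjusted p = 9.88e-06) and Nsg1 (1.23, adjusted p = 5.1e-09) were up at day 28. Clu fell by 1.34 at day 28 (adjusted p = 2.35e-05) and by 1.16 at day 90 (adjusted p = 0.000564). At day 90, Trib3 was higher (1.53, adjusted p = 1.9e-05), and Mug1 (-1.48, adjusted p = 6.08e-06), Lcat (-1.09, adjusted p = 1.55e-07) and the transcription factor Zbtb16 (-1.57, adjusted p = 0.000331) were lower. ER stress and chaperone genes rose, with 8 of 16 members up, 2 down and 6 not passing (10 and 2 adjusted over the list alone; adjusted p = 0.00454, adjusted p = 0.408 with an estimated correlation). At day 28, 8 were up and 1 down (9 and 1 adjusted over the list alone; adjusted p = 0.000131, adjusted p = 0.131 with an estimated correlation). Median centring ended both calls. Ribosomal protein genes had 6 of 36 up and 0 down in both adjustments (adjusted p = 0.00202, adjusted p = 0.477 with an estimated correlation), a call that ended without replicate 1 (adjusted p = 0.0548). At day 90, 16 of 37 were up and 0 down (25 and 0 adjusted over the list alone; adjusted p = 1.04e-12, adjusted p = 0.176 with an estimated correlation). Heat shock proteins had 3 of 11 up and 0 down in both adjustments (adjusted p = 0.0429, adjusted p = 0.269 with an estimated correlation). At day 7, mitochondrial fatty acid oxidation went down, with 3 of 23 members lower and 0 higher (9 and 0 adjusted over the list alone; adjusted p = 1.17e-07, adjusted p = 0.109 with an estimated correlation). So did peroxisomal oxidation, with 2 of 22 lower (5 adjusted over the list alone; adjusted p = 0.0019, adjusted p = 0.147 with an estimated correlation). On the mean over days, which includes day 1 with its bright Reg3a and Reg3b control, injury and Reg family genes fell. In both adjustments 8 of 18 members were down and 0 up (adjusted p = 0.00202, adjusted p = 0.00837 with an estimated correlation). The PPARα target list had 5 up and 5 down of 32 (7 and 5 adjusted over the list alone; adjusted p = 0.487, adjusted p = 0.741 with an estimated correlation). Tested on the mean over days, 22.7% of all features passed with Wy20. At any day 4973 differed from the control pool (2100 higher, 2873 lower), with 872, 135, 3577 and 2376 at the 4 days. Median centring gave 1823 with 25% of them higher, against 42.2% in the main count, and leaving out replicate 2 gave 1853.

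The third question was what DEHP changed. At day 1, the metal-binding protein gene Mt1 was 5.83-fold higher with DEHP (2.54 ± 0.11, adjusted p = 7.8e-20; treated level 11.06, control 8.47) and Ech1, an isomerase of fatty acid oxidation (0.81, adjusted p = 0.000354). Dusp6 was higher at day 28 (1.70, adjusted p = 2.87e-05), with a treated level of 8.42 and a control level of 6.97, against 9 and 10.08 at day 1 and 7.37 and 8.82 at day 7. Also higher were Agpat1 at day 28 (1.37, adjusted p = 1.73e-05, n = 2), Trib3 at day 28 (1.32, adjusted p = 8.92e-05) and Azgp1 at days 28 (0.71, adjusted p = 0.000181) and 90 (1.04, adjusted p = 3.27e-07). At day 90 the deubiquitinase gene Usp10 gained 1.21 ± 0.08 (adjusted p = 2.99e-13), while Clu (-1.48, adjusted p = 5.32e-06), Mug1 (-1.51, adjusted p = 8.47e-07) and Zbtb16 (-1.56, adjusted p = 8.78e-05) were lower.

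PPARα targets rose with DEHP at day 1, with 4 of 32 members up and 0 down (8 and 1 adjusted over the list alone; adjusted p = 7.23e-05, adjusted p = 0.149 with an estimated correlation). On the mean over days the list was not called, with 4 up and 0 down in both adjustments (adjusted p = 0.17, adjusted p = 0.579 with an estimated correlation). Mitochondrial fatty acid oxidation had 3 of 23 up at day 1 (5 up and 1 down adjusted over the list alone; adjusted p = 4.68e-05, adjusted p = 0.149 with an estimated correlation). At day 7 it went the other way with 1 member down (6 down and 1 up adjusted over the list alone; adjusted p = 4.67e-05, adjusted p = 0.184 with an estimated correlation). Over the days, 4 were up and 0 down (6 and 1 adjusted over the list alone; adjusted p = 0.00461, adjusted p = 0.43 with an estimated correlation), a call that median centring ended (adjusted p = 0.212). Circadian clock genes rose at day 7, with 2 of 10 members up and 0 down (5 and 0 adjusted over the list alone; adjusted p = 2.66e-06, adjusted p = 0.0471 with an estimated correlation), and no alternative ended that call. The transcription factor gene Klf9, which is outside that list, gained 0.90 at day 7 (adjusted p = 0.000172). On the mean over days 5 clock genes were up and 1 down in both adjustments (adjusted p = 0.0182, adjusted p = 0.43 with an estimated correlation). Ribosomal protein genes had 9 of 37 up and 0 down (14 and 0 adjusted over the list alone; adjusted p = 1.12e-07, adjusted p = 0.43 with an estimated correlation). Rps16 was higher at day 90 (0.59, adjusted p = 1.82e-06) and Rpl41 lower (-1.60, adjusted p = 4.01e-07). Injury and Reg family genes fell in 8 of 18 members with 0 up in both adjustments (adjusted p = 0.00224, adjusted p = 0.0116 with an estimated correlation), a call that ended without day 1 (adjusted p = 0.1). Tested on the mean over days, 14.6% of all features passed with DEHP. At any day 5408 differed from the control pool (2630 higher, 2778 lower), with 933, 170, 2208 and 4607 at the 4 days. Median centring gave 1590 with 35.8% of them higher, against 48.6% in the main count, and leaving out replicate 2 or 3 gave 1749 and 2577.

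**Figure D3:**
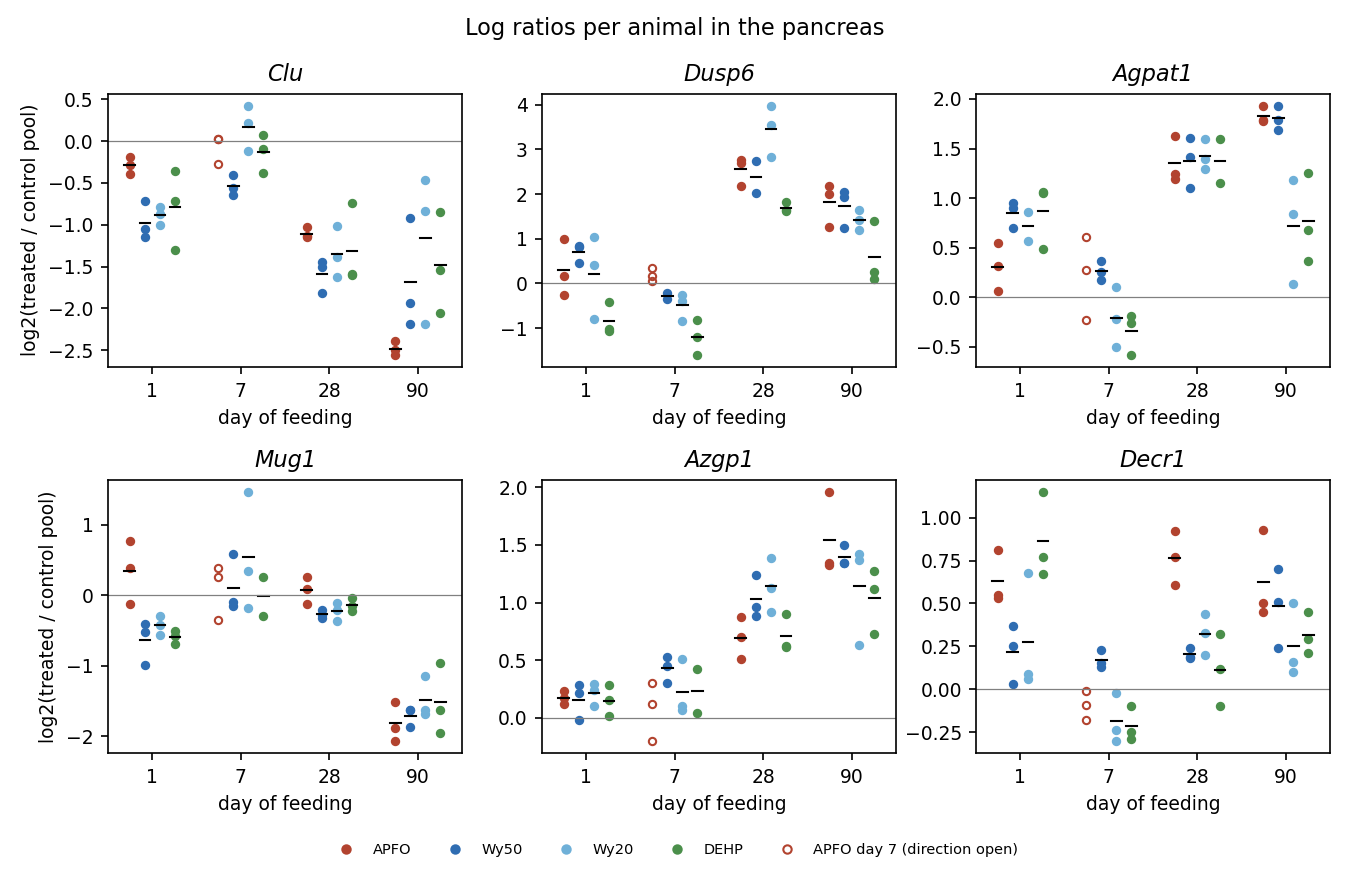
Log2 ratios of treated over control RNA for 6 genes in pancreas by day of feeding, with a point per Cy5 array (1 per rat), a bar at the group mean and open points for APFO at day 7, whose direction is not settled. Clu lies lowest with APFO at day 90 (-2.48), Dusp6 highest with Wy20 at day 28 (3.45), and Mug1 stands below 0 at day 90 in all 4 series. If the series shared a control pool at a day, their agreement is not independent.

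In isolated acinar cells the question was which changes lie in the acinar cell itself. With APFO, Clu (-1.22 ± 0.24, adjusted p = 0.00476) and Spp1 (-1.48 ± 0.19, adjusted p = 0.000821) were lower at day 28, and Azgp1 (1.22 ± 0.16, adjusted p = 0.000821) and the urokinase gene Plau (1.29, adjusted p = 0.00393) were higher. With Wy50, Dusp6 was 4.73-fold higher at day 28 (2.24 ± 0.25, adjusted p = 0.000269), as was the zymogen granule gene Cuzd1 (1.77 ± 0.20, adjusted p = 0.00045) and the glutaminase gene Gls2 (1.05 ± 0.14, adjusted p = 0.000669). Spp1 (-1.51 ± 0.19, adjusted p = 0.000639), the metalloprotease inhibitor Timp2 (-1.24 ± 0.09, adjusted p = 6.71e-06) and the stress-responsive transcription factors Jun (-1.36 ± 0.21, adjusted p = 0.00122) and Atf3 (-1.08 ± 0.16, adjusted p = 0.000981) were lower. Spp1 is also on the duct cell list and Timp2 on that of fibroblasts and stellate cells. The other genes that the naming rule took with Wy50 from these lists and the islet list had negative means over days. They were Onecut1 (-0.26), Cldn3 (-0.18), Bgn (-0.31), S100a4 (-0.30), Dcn (-0.22), Ppy (-0.56) and Chgb (-0.18), and none passed on that mean. Whether the share of other cells differed between preparations was not tested. Cyp4a1, a classical PPARα target of liver, had a mean over days of 0.03 with APFO (adjusted p = 0.979) and 0.04 with Wy50 (adjusted p = 0.873). The insulin gene Ins2 had means of 0.20 and 0.03 (adjusted p = 0.919 and 0.971) and Reg3b of -0.51 and -0.47 (adjusted p = 0.903 and 0.74). In the F-test over days Cyp4a1 did not pass with APFO (adjusted p = 0.245), but passed without the bright replicate 3 of day 7 (adjusted p = 0.0294) and with all arrays and a dye term (adjusted p = 0.0104), as did Reg3b with Wy50 with all arrays (adjusted p = 0.00134). The fit of all arrays counts repeat hybridisations as separate rats, so its p-values can be too low. At day 28 the control channel of Wy50 acinar cells stood apart from days 1 and 7 for Cuzd1 (11.64, against 13.28 and 13.40) and Spp1 (10.39, against 8.92 and 8.41), where the treated channel ranged from 13.17 to 13.35 and from 8.32 to 8.91.

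The injury and Reg family list fell in both acinar series at day 28. With Wy50, 7 of 22 members were down and 0 up in both adjustments (adjusted p = 0.000583, adjusted p = 0.0336 with an estimated correlation), which no alternative ended. With APFO, 6 were down and 0 up in both adjustments (adjusted p = 0.00256, adjusted p = 0.0983 with an estimated correlation), which ended without replicate 3 (adjusted p = 0.0739). On the mean over days, 0 members passed with APFO (1 down adjusted over the list alone; adjusted p = 0.00367, adjusted p = 0.0715 with an estimated correlation) and 0 with Wy50 (6 down adjusted over the list alone; adjusted p = 0.00986, adjusted p = 0.213 with an estimated correlation). Immediate early genes were lower with Wy50 at day 28, with 9 of 31 down and 1 up (10 and 2 adjusted over the list alone; adjusted p = 0.0031, adjusted p = 0.227 with an estimated correlation). Protease inhibitors were lower too, with 8 of 27 down and 0 up (9 and 2 adjusted over the list alone; adjusted p = 0.00252, adjusted p = 0.227 with an estimated correlation). The log ratios of the scanner software ended both calls. Timp2, a protease inhibitor of that list, is also on the list of fibroblasts and stellate cells, so other cells in the preparations may contribute, which was not tested. Ribosomal protein genes with APFO were higher at day 28, with 7 of 57 up (10 adjusted over the list alone; adjusted p = 0.0021, adjusted p = 0.778 with an estimated correlation), a call that ended without replicate 3 of every group (adjusted p = 0.6). At day 7 the list was called lower with 1 member down (14 adjusted over the list alone; adjusted p = 3.86e-12, adjusted p = 0.915 with an estimated correlation), but that call rested on the bright replicate 3 of this group and ended without that array alone (adjusted p = 0.626). Across features, this array correlated at -0.113 and -0.082 with the other Cy5 arrays of its group, which correlated at 0.245 with each other. PPARα targets were not called on the mean over days, with 0 of 37 passing with APFO (adjusted p = 0.599) and with Wy50 (2 up adjusted over the list alone; adjusted p = 0.342). On that mean, 11 and 16 of 35906 features passed at all. At day 28, 2 targets were up and 3 down with APFO (7 and 3 adjusted over the list alone; adjusted p = 0.594), and 3 up and 4 down with Wy50 (4 and 4 adjusted over the list alone; adjusted p = 0.452).

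In acinar cells with APFO, 1994 of 35906 features differed from the control pool at any day (813 higher, 1181 lower). Tested day by day, 7, 2 and 3470 passed at days 1, 7 and 28. For Wy50 the count at any day was 1651 (381 higher, 1270 lower), with 3, 211 and 2427 at the 3 days. Without the bright replicate 3 of APFO at day 7, the APFO counts were 3107 at any day and 0 at day 7. The day 1 calls with a symbol were Aqp8 (-1.01), Aldh1a4 (-0.76) and Mug1 (-1.67) with APFO and Aldh1a4 (-0.71, n = 2) and Mug1 (-2.20, n = 2) with Wy50, and that at day 7 with APFO was Rpl4 (-0.64). All of these ended without replicate 1 (adjusted p = 0.28, 0.12 and 0.276 for Aqp8, Aldh1a4 and Mug1 with APFO, 0.237 and 0.219 for Aldh1a4 and Mug1 with Wy50, and 0.866 for Rpl4). Aqp8 and Mug1 with APFO also ended without replicate 3 (0.317 and 0.142), Aldh1a4 and Mug1 with Wy50 without replicate 2 (0.205 and 0.0531), and Rpl4 without either (0.148 without replicate 2, 0.109 without replicate 3, 0.051 without the bright array alone). With the scanner software Aqp8, Rpl4 and Mug1 ended (adjusted p = 0.101, 0.233 and 0.138 with APFO, 0.0668 for Mug1 with Wy50). Without background subtraction Aqp8 and Mug1 ended (0.0619 and 0.0593 with APFO, 0.0915 for Mug1 with Wy50). Median centring ended Aqp8 and Mug1 with APFO (0.201 and 0.164) and Aldh1a4 with Wy50 (0.168). A replicate block ended Aqp8 with APFO (0.0959) and Mug1 with Wy50 (0.0633), and the fit of only these arrays ended Rpl4 (0.409). Where these calls ended, the changes of the same probes kept their sign: -0.70 to -1.26 for Aqp8, -1.42 to -2.57 for Mug1 with APFO, -1.84 to -3.66 for Mug1 with Wy50, -0.78 for Aldh1a4 with APFO, -0.63 to -0.75 with Wy50, and -0.58 to -0.76 for Rpl4. Another Mug1 probe gave 0.03 with APFO and -0.08 with Wy50 (adjusted p = 0.908 and 0.927). These counts rest on few arrays: leaving out 1 replicate number left 10 to 470 features with APFO and 62 to 547 with Wy50. Median centring gave 4796 and 4616, and no dye correction 7444 and 4575. The log ratios of the scanner software gave 936 with APFO, 52.6% of them higher against 40.8% in the main count.

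Differences between compounds were tested directly, although the dietary levels differed (300 ppm APFO, 50 ppm Wy, 12000 ppm DEHP). Mgp at day 90 was higher with APFO than with Wy50 by 1.51 ± 0.21 (1.83 against 0.33, adjusted p = 9e-05) and than with DEHP by 1.80 (adjusted p = 2.18e-06). Mt1 at day 1 was higher with DEHP than with Wy50 by 2.54 ± 0.15 (adjusted p = 1.72e-14), where the Wy50 mean was 0. At day 1, Epcam, an adhesion protein of epithelial cells, was higher with APFO than with DEHP by 1.07 ± 0.16 (0.53 against -0.54, adjusted p = 3.95e-05). PPARα targets stood higher with DEHP than with Wy50 at day 1, with 0 of 32 members passing alone (4 up adjusted over the list alone; adjusted p = 2.05e-05, adjusted p = 0.297 with an estimated correlation). Oxidative phosphorylation was higher with APFO than with DEHP at day 28, with 5 of 11 members up and 0 down in both adjustments (adjusted p = 0.00429, adjusted p = 0.0495 with an estimated correlation). The injury and Reg family list was lower with APFO than with DEHP at day 90, with 4 of 18 down and 0 up in both adjustments (adjusted p = 0.00407, adjusted p = 0.0154 with an estimated correlation).

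APFO and Wy50 differed in pancreas for 7884 features (4116 higher with APFO, 3768 lower), with 2584, 51, 4351 and 1704 at the 4 days. APFO and DEHP differed for 7755 (4118 higher, 3637 lower), with 3284, 35, 3750 and 1829. DEHP and Wy50 differed for 868 (568 higher with DEHP, 300 lower), with 15, 1, 0 and 2858 (457 features had an unadjusted p under 0.05 at day 28 by limma). The day 7 counts with APFO rest on arrays whose direction is not settled: with arrays 1 and 4 turned they were 4987 against Wy50 and 4550 against DEHP, and with arrays 2, 3 and 5 turned 4172 and 2934. A missing call does not show that compounds acted alike. The DEHP and Wy50 count was 1473 or 1406 with APFO day 7 arrays turned either way, 1411 without them, 2152 with only these treatments in the fit, 1553 with all arrays and 254 with the date as a block. The APFO and Wy50 count was 3634 with only these treatments, 4661 with all arrays, 4984 with the scanner software and 3625 with the date block, and the APFO and DEHP count 4007, 5152 with all arrays, 5138 without day 1 and 4814 with the date block. Without replicate 2 the counts for APFO and Wy50, APFO and DEHP, and DEHP and Wy50 were 929, 1573 and 7, and without replicate 3 1305, 1589 and 7. Without replicate 1 DEHP and Wy50 differed for 2044. Median centring gave 4165 with 35.4% higher against 52.2%, an APFO and DEHP share of 37.9% against 53.1%, and for DEHP and Wy50 20 features with 40% higher against 65.4%. On days when both groups shared a processing date, DEHP and Wy50 differed for 7 features (days 1, 7 and 28 together) and APFO and DEHP for 1829 (day 90). APFO had no date in common with Wy50 in pancreas, so date and treatment cannot be told apart there. The same holds for APFO and DEHP at days 1, 7 and 28 and for DEHP and Wy50 at day 90. The differences between APFO and DEHP in Epcam at day 1 and oxidative phosphorylation at day 28 fall on such days.

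Between the levels of Wy, 1740 features differed (810 higher with Wy50, 930 lower), with 297, 0, 3 and 2083 at the 4 days (1452 with an unadjusted p under 0.05 at day 7 by limma). At day 28 the 3 were Oat (-0.82, adjusted p = 0.0198), Nolc1 (-0.67, adjusted p = 0.0432) and a feature with no symbol (-0.83, adjusted p = 0.0198). Oat ended without replicate 1, 2 or 3 (adjusted p = 0.281, 0.11 and 1) and Nolc1 without replicate 2 or 3 (0.756 and 1). Both ended with the scanner software (0.481 for Oat, 0.101 for Nolc1), under median centring (0.0694 and 0.979) and with the date block (0.217 and 0.4), and Oat with only these treatments in the fit (0.054). Where they ended, Oat stood at -0.67 to -1.38 and Nolc1 at -0.63 to -0.79. At day 90 the collagen-modifying enzyme gene Plod2 was higher with Wy50 by 0.78 ± 0.12 (adjusted p = 0.000197), and Agpat1 by 1.09 (1.80 against 0.72, adjusted p = 0.00108), a call that median centring ended. ER stress genes stood lower with Wy50 than with Wy20 at day 28 while 0 of 16 members passed in either adjustment (adjusted p = 0.000689, adjusted p = 0.141 with an estimated correlation; median centring ended the call). Within the shared date of day 90, 2038 features differed. At days 1, 7 and 28 Wy50 and Wy20 lay on different dates, so date and level cannot be told apart there. Without replicate 1, 2 or 3 the count at any day was 1102, 14 and 786, with median centring 125 and with the date as a block 1069.

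Isolated acinar cells gave nearly no single feature that differed between APFO and Wy50 past the test. The compounds differed for 1 feature at any day, which has no symbol (mean 0.16, adjusted p = 0.0192 in the F-test), although 1290 had an unadjusted p under 0.05 by limma. At day 1 and day 28 the counts were 0 (1142 and 995 with an unadjusted p under 0.05) and at day 7 3, all without a symbol. Without the bright APFO array at day 7 the counts at any day and at day 7 were 0. Without replicate 2 or 3 the count at any day was 0. Of the 31 gene lists, limma camera called 4 on the mean over days (1 higher and 3 lower with APFO). It called 4 at day 7, all lower, and 3 at day 28 (1 higher, 2 lower). With an estimated correlation 0 lists were called.

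Responses of whole pancreas and of isolated acinar cells were compared over the 5213 features on both array sets. The APFO response differed for 1356 features (777 higher in pancreas, 579 lower), with 380, 24 and 981 at days 1, 7 and 28. The log ratio of Reg3a at day 1 was lower in pancreas than in acinar cells (-6.32 against -1.02, difference -5.30 ± 0.95, adjusted p = 0.000284). It went with a bright pancreas control channel, at 16.89 at day 1 against 10.44 to 11.14 at later days, while the treated level was 10.58. The treated level thus lay within the range of the later control levels. In treated acinar cells the Reg3a level was 14.75 at day 1, and 11.49 and 9.43 at days 7 and 28. Whether treatment held back a rise at day 1 in pancreas cannot be told from these levels. The log ratios of the transcription factor Foxe1 at day 1 (0.10 against -1.76, difference 1.86 ± 0.27, adjusted p = 8.46e-06) and the immediate early gene Ier2 at day 28 (0.86 against -0.88, difference 1.74 ± 0.23, adjusted p = 1.25e-06) were higher in pancreas. Foxe1 was not called against control in acinar cells at day 1. Its treated level there was 8.97 at day 1, and 8.10 and 7.84 at days 7 and 28, so the low ratio did not go with a dim treated channel. Higher and lower refer to log ratios in this paragraph, not to levels. Oxidative phosphorylation was higher in pancreas at day 28, with 6 of 9 members up and 0 down (7 and 0 adjusted over the list alone; adjusted p = 3.19e-05, adjusted p = 0.0186 with an estimated correlation). The Wy50 response differed for 131 features (101 higher in pancreas, 30 lower), with 21, 55 and 23 at the 3 days. Immediate early genes were higher in pancreas at day 28, with 4 of 18 up and 0 down (9 and 0 adjusted over the list alone; adjusted p = 1.46e-06, adjusted p = 0.00533 with an estimated correlation). Cell preparation and array design differed between the materials. Leaving out replicate 2 left 189 and 5 features, replicate 3 526 and 42, and replicate 1 1530 and 44. With only the APFO arrays in the fit the APFO count was 26, with all arrays 829, without dye correction 2173, and with the day 7 arrays turned either way 2324 or 2040. At day 7 it was then 1264 with arrays 1 and 4 turned and 785 with arrays 2, 3 and 5 turned, and 76 without the bright acinar array. At day 1 it was 602, 584 and, without APFO pancreas at day 7, 609. Without the bright acinar array the Wy50 response at day 28 differed for 39. The Wy50 count was 26 under median centring, 254 without background subtraction, 244 with all arrays, 446 without dye correction, 58 with the date block and 72 without day 1. Median centring gave a higher share of 37.6% against 57.3% for APFO and 88.5% against 77.1% for Wy50, and the scanner software 50.5% for Wy50.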

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

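The tests of both Reg explanations, of a shifted day 28 control pool, of the treated channel at day 28 and of exchanged dye labels were chosen only after the result was seen. Groups held 3 Cy5 arrays or fewer and were not tested for outlying samples.

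Differences between treatments or materials at any day stood out by limma's F-test of the difference itself. In pancreas 7884 features differed between APFO and Wy50, 868 between DEHP and Wy50, 7755 between APFO and DEHP, and 1740 between Wy50 and Wy20. In acinar cells 1 feature differed between APFO and Wy50. The response in pancreas differed from that in acinar cells for 1356 features with APFO and 131 with Wy50. Responses also differed between days for 11203 features with APFO, 4849 with Wy50, 2132 with Wy20 and 3713 with DEHP in pancreas, and for 2471 with APFO and 237 with Wy50 in acinar cells.

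Other splits of the arrays of both groups within days were drawn 100 times, the real split included. For APFO against Wy50 only 1 split, the real one, reached 7884 (highest other 6853), for DEHP against Wy50 1 reached 868 (highest other 541), and for Wy50 against Wy20 1 reached 1740 (highest other 647). For APFO against DEHP 2 splits reached 7755 (highest other 8181), for the APFO response between materials 2 reached 1356 (highest other 1411), and for the Wy50 response 1 reached 131 (highest other 47). At most 2 of the 100 splits, the real one included, reached each of these 6 counts. Chance assignment of the arrays is thus unlikely for them. It cannot be excluded for APFO against DEHP and for the APFO response between materials, where another split called more. Differences that go with dates cannot be excluded for any of them. For APFO against Wy50 in acinar cells 32 splits gave 1 call or more (real count 1), chance cannot be excluded, and the highest other split called 26.

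Reg3b and Reg3a stood very low at day 1 in all 4 pancreas series, for Reg3b with APFO on 1 array only. The treated channel at day 1 lay -0.20 log2 units from the control channel of other days (median of 8 pairs of gene and treatment, -0.75 to 0.97). This argues against a level in treated pancreas below that of controls of other days. It cannot tell whether treatment held back a rise that the day 1 controls showed. The control channel at day 1 lay at least 6.40 above that of other days (5.86 to 6.93, lower bounds in the Wy50, Wy20 and DEHP series, where it was saturated), so a high level of these transcripts in the day 1 control RNA may account for the low ratios. Whether that came from the control rats, from handling or from the RNA was not tested.

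At day 28, 1083 features were called in the same direction in all 4 pancreas series, 379 higher and 704 lower, where independent lists would share 1.1 and 2.7, a simulated shared control with no effect gave up to 1032 in 10 simulations, and the control could not be split. Of the 269 such features on both array sets, 267 had the same sign in acinar cells at day 28 (99.3%, against 43.1% at day 1 and 77.7% at day 7), which argues against a shift peculiar to the pancreas RNA pool. The control channel at day 28 was shifted against days 1 and 7 by a median share of 1.118 of the change (quartiles 0.562 and 1.636), so a shift of the control rats at day 28 may underlie much of it; whether acinar controls came from the same rats is not given in the sources used here. The treated channel moved by a median share of -0.332 (quartiles -0.841 and 0.25), which argues against a common response over steady controls. A response on top of a shift with day or date in both channels stays open.

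Arrays 1 and 4 of APFO pancreas at day 7 ran against arrays 2, 3 and 5. An animal that responded the other way is argued against by a correlation of -0.304 across 200 features between array 1 as labelled and the reversed day 7 difference of the other series' control channel (-0.364 for array 4, and 0.187, 0.325 and 0.104 for arrays 2, 3 and 5), if the series shared that control. With its other dye label, array 1 correlated at 0.539 across features with the mean of APFO days 1 and 28, so exchanged dye labels of arrays 1 and 4 are a candidate explanation. The correlation with fold changes in the authors' deposited table rose by 0.374 when both arrays were turned (0.437 as labelled, 0.811 turned, 3915 features), which may mean that those folds rest on other dye labels. Genes are not independent replicates, and no biological explanation beyond the single animal was tested.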

How the results depend on the processing

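The fits without day 1, without saturated features, without DEHP pancreas day 7 replicate 1, without APFO acinar day 7 replicate 3, on shared dates, and with APFO day 7 arrays turned or left out were chosen only after the result was seen. Dropping the dim-feature filter or saturated features, or DEHP pancreas day 7 replicate 1 where it applies, kept each count at any day within 1.5 times. Many changes were small, so counts moved with the scaling, the spread pooled and the arrays used; the cause was not tested except where named. Averaging swapped with original arrays was not run, since the swapped rat could be told in 10 of 16 pancreas and 4 of 6 acinar groups. A date block could not be estimated for acinar cells, where each group lies on 1 date. In pancreas only 1 of 16 groups lies on more than 1 date, so the estimate of the date block there rests on little. Acinar arrays were as dim as 33.37% of probes above background, which limits dim genes there.

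With the scanner software's log ratios, APFO minus Wy50 gave 4984 features, APFO in acinar cells 936, Wy50 in acinar cells 689 and their difference 10. Without background subtraction the acinar difference gave 0 and the Wy50 response between materials 254. Median centring gave 4105 for Wy50, 1823 for Wy20, 1590 for DEHP, 4165 for APFO minus Wy50, 20 for DEHP minus Wy50, 125 for Wy50 minus Wy20, 4796 and 4616 for APFO and Wy50 in acinar cells, 0 for their difference and 26 for the Wy50 response. All arrays with a dye term gave 4661 for APFO minus Wy50, 1553 for DEHP minus Wy50, 5152 for APFO minus DEHP, 4946 and 5945 in acinar cells, 3 for their difference, and 829 and 244 for the APFO and Wy50 responses. Repeat hybridisations count as separate rats in that fit. Without dye correction APFO and Wy50 in acinar cells gave 7444 and 4575 and the responses 2173 and 446. With only the treatments compared in the fit, APFO gave 6219, APFO minus Wy50 3634, DEHP minus Wy50 2152, APFO minus DEHP 4007, acinar cells 256 and 3316, and the APFO response 26.

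With the replicate number as a block, APFO in acinar cells gave 1267 and the acinar difference 0, and no other count at any day moved by over 1.5 times. Replicate numbers do not pair the rats: arrays with the same number correlated at a mean of -0.047 to 0.030 in their deviations from group means. With the date as a block Wy20 gave 2985, DEHP 3208, APFO minus Wy50 3625, DEHP minus Wy50 254, APFO minus DEHP 4814, Wy50 minus Wy20 1069 and the Wy50 response 58. On shared dates DEHP minus Wy50 gave 7 and APFO minus DEHP 1829, over fewer days. Without day 1, APFO minus DEHP gave 5138, the acinar difference 2 and the Wy50 response 72. With arrays 1 and 4 of APFO day 7 turned, DEHP minus Wy50 gave 1473 and the APFO response 2324. With arrays 2, 3 and 5 turned they gave 1406 and 2040. Without APFO day 7 DEHP minus Wy50 gave 1411, since the spread of that group enters the shared variance.

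Leaving out replicate numbers in turn gave ranges of 9266 to 14363 for APFO, 4108 to 8864 for Wy50, 1853 to 4252 for Wy20 and 1749 to 4341 for DEHP, which gave 5236 without DEHP pancreas day 7 replicate 1. The ranges were 929 to 9341 for APFO minus Wy50, 7 to 2044 for DEHP minus Wy50, 1573 to 8440 for APFO minus DEHP and 14 to 1102 for Wy50 minus Wy20. In acinar cells they were 10 to 470 for APFO, 62 to 547 for Wy50 and 0 to 1 for the difference, and for the responses 189 to 1530 with APFO and 5 to 44 with Wy50. Without APFO acinar day 7 replicate 3 alone they gave 3107, 2213, 0, 1590 and 157. Where Wy50 in acinar cells at day 1 was left with 1 array, that array was assumed to vary like the other groups.

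The printed genes are the steadier ones. Over all 863 values of genes taken by the naming rule, median centring ended the call of 271 and turned the sign of 36, and no dye correction turned 44. Leaving out replicate 2 ended the call of 342 of 859 and turned 14. Of 115 values from other probes of these genes, 34 had the other sign and 41 kept the sign without passing. For the printed results that turned, the cause was not tested. For digestive enzymes with APFO the list turned under median centring (adjusted p = 0.871) and without saturated features (0.884, and 0.77 at day 28). With Wy50 in acinar cells, ribosomal proteins turned under median centring (0.00746) and without dye correction (0.31), and digestive enzymes without dye correction (1.5e-09). Without dye correction the log2 mean over days of Spink1 with APFO was -0.134. Another probe of Mug1 gave 0.026 with APFO in acinar cells at day 1.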

Other observations

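No test in this part was chosen after the result was seen except the fits without day 1 and without saturated features. Several gene groups had members called in both directions in APFO pancreas, with no list call in the 6 series on the mean over days. Of all features, 51.1% passed on that mean with APFO (5214 higher, 4997 lower). Counts near that share, here and in the next paragraph, are no sign of a change of the group. Islet cell genes had 7 members up and 6 down of 25 with APFO (adjusted p from 0.0919 to 0.627 over the 6 series), and duct cell genes 5 up and 6 down of 16 (0.196 to 0.879). Protease inhibitors had 3 up and 7 down of 18 (0.055 to 0.432), and genes of acinar identity and secretagogue signalling 6 up and 3 down of 21 (0.426 or higher). Cell cycle genes had 4 up and 7 down of 22 (0.266 to 0.798). In lipid pathways, cholesterol synthesis had 8 up and 4 down of 17 (0.235 to 0.644) and fatty acid synthesis 7 up and 3 down of 19 (0.315 to 0.879). Peroxisomal oxidation ranged from an adjusted p of 0.533 to 0.879. Nrf2 targets had 5 up and 6 down of 25 (0.315 to 0.879), xenobiotic metabolism 5 up and 7 down of 19 (0.331 to 0.908), and oxidative phosphorylation 7 up and 1 down of 11 (0.145 to 0.737). Interferon response genes had 1 up and 4 down of 11 (0.342 to 0.94).

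Markers of other cell types and tissues gave no list call on the mean over days either. With APFO, lymphocyte genes had 7 up and 6 down of 27 (adjusted p from 0.266 to 0.943 over the 6 series), macrophage and granulocyte genes 2 up and 6 down of 16 (0.533 to 0.965), fibroblast genes 7 up and 9 down of 22 (0.376 to 0.94), smooth muscle genes 0 up and 4 down of 7 (0.235 to 0.879) and endothelial genes 1 up and 3 down of 12 (0.501 to 0.94). Red blood cell genes had 1 up and 1 down of 5 (0.0645 to 0.891), fat cell genes 1 up and 3 down of 17 (0.145 to 0.644), liver genes 8 up and 9 down of 30 (0.156 to 0.866) and intestine genes 6 up and 1 down of 15 (0.267 to 0.879). Adjusted over the list alone, the APFO counts of both paragraphs were the same except for 7 duct and 8 xenobiotic genes down and 8 fibroblast genes up. Which of these markers acinar cells express was not tested.

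Isolated acinar cells of Wy50 rats had further list calls on the mean over days in which few single members passed. Mitochondrial fatty acid oxidation was higher with 0 of 27 members past the test (2 up adjusted over the list alone; adjusted p = 0.0153, adjusted p = 0.458 with an estimated correlation). Median centring, no dye correction and leaving out replicate 3 each ended the call. Amino acid response genes were higher with 0 of 20 (2 up and 1 down adjusted over the list alone; adjusted p = 0.00902, adjusted p = 0.483 with an estimated correlation). Immediate early genes were lower with 1 up and 1 down of 31 (2 and 8 adjusted over the list alone; adjusted p = 0.00189, adjusted p = 0.213 with an estimated correlation). Digestive enzymes had 0 of 21 past the test (3 up adjusted over the list alone; adjusted p = 0.00189, adjusted p = 0.711 with an estimated correlation) and ribosomal proteins 0 of 57 (adjusted p = 0.0493, adjusted p = 0.761 with an estimated correlation). Both were higher, but without dye correction both turned, and the ribosomal list turned under median centring too.

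Among genes fixed to be named, the cholecystokinin receptor gene Cckar had means over days in pancreas of 0.19 with APFO (adjusted p = 0.0744), -0.11 with Wy50 (adjusted p = 0.408), 0.17 with Wy20 (adjusted p = 0.204) and 0.15 with DEHP (adjusted p = 0.327). With APFO it passed the F-test over days (adjusted p = 0.0303), a call that ended without replicate 2 or 3 (adjusted p = 0.199 and 0.39), with only APFO in the fit (0.341), under median centring (0.0727), without background subtraction (0.0798) and with the date block (0.127). With Wy50, Wy20 and DEHP it did not pass the F-test. It passed with all arrays and a dye term (adjusted p = 0.0012, 0.0297 and 0.00117), a fit that counts repeat hybridisations as separate rats. It also passed with only that treatment in the fit (0.0144, 0.00473 and 0.000688) and without replicate 1 (8.67e-05, 0.0267 and 0.00297). By day it stood at 0.61 with APFO at day 1, -0.55 with Wy50 at day 90 and 0.49 with DEHP at day 90 (adjusted p = 0.0165, 0.0164 and 0.0485). All 3 ended under median centring (0.102, 0.347 and 0.493) and without replicate 2 (0.0959, 0.202 and 0.19) or 3 (0.235, 0.255 and 0.192). The APFO call also ended with only APFO in the fit (0.301) and with the date block (0.054), and the DEHP call with the scanner software (0.0783), the replicate block (0.0535) and the date block (0.115). The trypsin inhibitor gene Spink1 went opposite ways by day with APFO, with 0.89 at day 1 (adjusted p = 0.000661), 0.23 at day 7, -0.60 at day 28 (adjusted p = 0.00563) and 0.40 at day 90. Its mean over days was 0.23 (adjusted p = 0.0333), whose sign turned without dye correction. The day 1 call ended without replicate 3 (adjusted p = 0.114) and with only APFO in the fit (0.139), and the day 28 call without replicate 2 or 3 (0.0678 and 0.113) and under median centring (0.324). Spots of the amylase gene Amy2a3 were saturated in acinar cells and the control channel of Angptl4 was not well above background at some days in pancreas, so no values are given for them.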
